A study of Homo sapiens with 6 samples.

How the data were processed

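RNA of U2OS cells, an established human osteosarcoma line, was measured 48 h after transfection with a miR-542-3p mimic (3 arrays) or with a negative control mimic (3 arrays). A microRNA mimic is a synthetic RNA duplex that acts in the cell like the mature microRNA. Per the labels' protocols, RNA was purified on columns with DNase treatment and turned into biotin-labelled cRNA, which was hybridised to Illumina bead arrays. The labels number the samples within each group but do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

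The authors deposited a non-normalized table with a signal intensity for each of 47323 probes on each array, and, per the file headers, a detection p-value beside each intensity. Every intensity was positive. The scanner software, any background subtraction and the slide of each array are not given in the sources used here. A second table deposited by the authors holds values on the log2 scale. Its 6 columns have nearly equal medians, from 7.138 to 7.139, and order the probes as the intensities do. Values of the same rank differed by at most 0.011 between columns, so the columns share nearly 1 distribution. Each column correlated with log2 of its array's intensity at r above 0.9999, with no sign of a subtraction beyond any already in the intensities. The software behind them is not given in the sources used here. They served as an alternative.

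Probes were paired with genes through GEO's annotation of the array, and symbols were checked by Entrez identifier against a RefSeq gene table of assembly GRCh38.p14. No symbol needed an update, and 39 probes with 1 gene had no match there and kept their symbol. In that annotation 30113 probes had 1 gene, 8 had several and 17202 had none listed here. No gene was named from a probe with several. Of 1060 different genes in the gene lists, 61 had no probe listed here, and those genes were not analysed here.

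Intensities were background-corrected with nec of limma 3.58.1 in R 4.3.3, then quantile-normalized and put on the log2 scale. The background step used an offset of 16 and the negative-control mean and SD inferred from the detection p-values. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept. A gene was represented by its probe with the highest mean over all 6 arrays. This left 14775 rows, of which 10734 were genes and 4041 were probes without a single gene. The groups were compared with limma's lmFit and eBayes, with no covariate, and Benjamini-Hochberg adjustment over all rows. A gene is called higher or lower at an adjusted p under 0.05. Changes are log2 differences, mimic minus control, with limma's standard error. The number of arrays limits the precision. A gene detected on no array of 1 group has only a bound there, given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal.

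Before the data were examined, 28 gene lists were fixed from general knowledge: pathways, complexes, reported miR-542-3p targets, and markers of other cell types. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list's members changed more than other genes. Fry asks whether they changed, without comparing them with other genes. The rule for named genes, also fixed then, took the 12 largest falls and 12 largest rises among called genes whose arrays separate by group, every measured reported target, up to 4 members of each other list by smallest adjusted p, and MDM2 and CDKN1A in any case. A further gene of that rule is not reported here. The text gives examples from these. Another 18 genes were added to the alternatives after their values were seen, and other list members are named in the text to say which genes make up a count.

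The alternatives were other background steps, normalizations, dim-probe filters, probe rules, variance models, array weights, thresholds, the replicate number as a block, leaving out each array in turn, and the deposited log2 values. A planned comparison of genes with and without a match to the microRNA's seed was not run, since no transcript sequence was used here. Simulated data of 14775 rows had the real rows' means and residual SDs, with the SDs shuffled over rows, so spread did not follow signal. The background step, normalization, filter and probe choice were not rerun on them. The fit recovered 5.97% of rows changed by 0.5 on the log2 scale, 59.7% of those changed by 1 and 97.0% of those changed by 2. Of its calls, 8.48% were unchanged rows. Camera called 4 of 4 shifted lists and 1 of 24 unshifted lists. Only 200 simulated rows were changed, far fewer than in the real data, so the recovery shares may differ there. The noise was independent between rows and the lists were random rows. The simulation therefore cannot show how often camera calls unshifted lists whose members are correlated.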

Results

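Gene expression was compared between U2OS cells given a miR-542-3p mimic and cells given a negative control mimic, to ask which transcripts change when this microRNA is raised. Each group had 3 arrays. Median signal ranged from 132.2 to 151.4 over the 6 arrays, and 17848 to 18652 of the 47323 probes were detected. Arrays of the same group correlated at 0.983 to 0.990 and arrays of different groups at 0.956 to 0.968, over probes. The first principal component held 65.0% of the variance and separated the groups.

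Expression of BIRC5, which encodes the apoptosis inhibitor and mitotic protein survivin, fell 9.69-fold with the mimic, from 11.96 ± 0.03 to 8.69 ± 0.37 on the log2 scale (SD, n = 3 per group; limma adjusted p = 7.8e-05). TAGLN, an actin-binding protein of smooth muscle, fell by 3.45 ± 0.41 (SE) on the log2 scale. PDIA6, a protein disulfide isomerase of the endoplasmic reticulum, fell by 3.03 ± 0.14, EBP, a sterol isomerase, by 2.77 ± 0.14, and ARPC1A, a subunit of the actin-nucleating Arp2/3 complex, fell by 2.76 ± 0.13. The other large falls were those of DTNA, CREG1, SCARA3, GPRIN1 and KATNAL1, between 2.64 and 3.00 on the log2 scale, with SCARA3, GPRIN1 and KATNAL1 detected on 1 of 3 mimic arrays. Dimmer probes of SCARA3 gave -1.23 and -0.27, the last not called (limma adjusted p = 0.516). ARHGDIB and LCP1 were detected on all control arrays and on no mimic array, and were lower by at least 5.05-fold each. These bounds and the falls of dim genes depend on the background step: with no background correction the changes were -1.55 for ARHGDIB, -1.26 for LCP1, -1.55 for SCARA3, -1.30 for GPRIN1 and -1.38 for KATNAL1, against -2.96 for BIRC5.

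GDF15, a stress-induced cytokine, was detected on no control array and on all mimic arrays, and was at least 10.2-fold higher with the mimic. PSTPIP2 was at least 7.63-fold higher, CYSRT1 at least 5.87-fold, CDH10 at least 4.89-fold and NECTIN4 at least 3.69-fold. ACTA2, smooth muscle actin, rose 7.47-fold, from 6.60 ± 0.14 to 9.50 ± 0.20 (SD, n = 3). INKA2, SUGCT, FEZ1 and DGKA rose by 2.86, 2.81, 2.77 and 2.64 on the log2 scale. Dimmer probes of FEZ1 gave 1.88, 0.81 and 0.26, the last not called (limma adjusted p = 0.521). PADI4, detected on 1 control array, rose by 2.58. TAB3 was at least 4.83-fold higher by its brighter probe, with a change of 2.65. Its other probe gave 0.83, and that probe stood for the gene when a mimic array was left out. The call then ended without mimic replicate 1 (0.84) or replicate 3 (0.66), and the change was 0.98 without replicate 2. With no background correction the changes were 2.14 for GDF15, 1.59 for PSTPIP2, 1.39 for CYSRT1, 1.21 for CDH10, 1.33 for NECTIN4, 1.66 for FEZ1, 1.75 for DGKA, and 1.23 for both PADI4 and TAB3, so the bounds above hold only with the background step.

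In all, 2833 of 10734 genes changed (limma, adjusted p under 0.05). With the mimic, 1358 were higher and 1475 were lower. At least 2-fold changes were found for 325 higher and 495 lower genes, and at least 4-fold changes for 36 higher and 55 lower genes. The 3 mimic arrays lay on one side of the 3 control arrays for 45.0% of genes, against 10% by chance. Without control replicate 1 the count was 1860, with 858 higher. Without mimic replicate 1 it was 1868, with 809 higher, and without mimic replicate 3 the higher genes numbered 873. At an adjusted p under 0.01 there were 1430 changed genes, and 1345 when a change above 1.2-fold was tested with limma's treat.

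**Figure D1:**
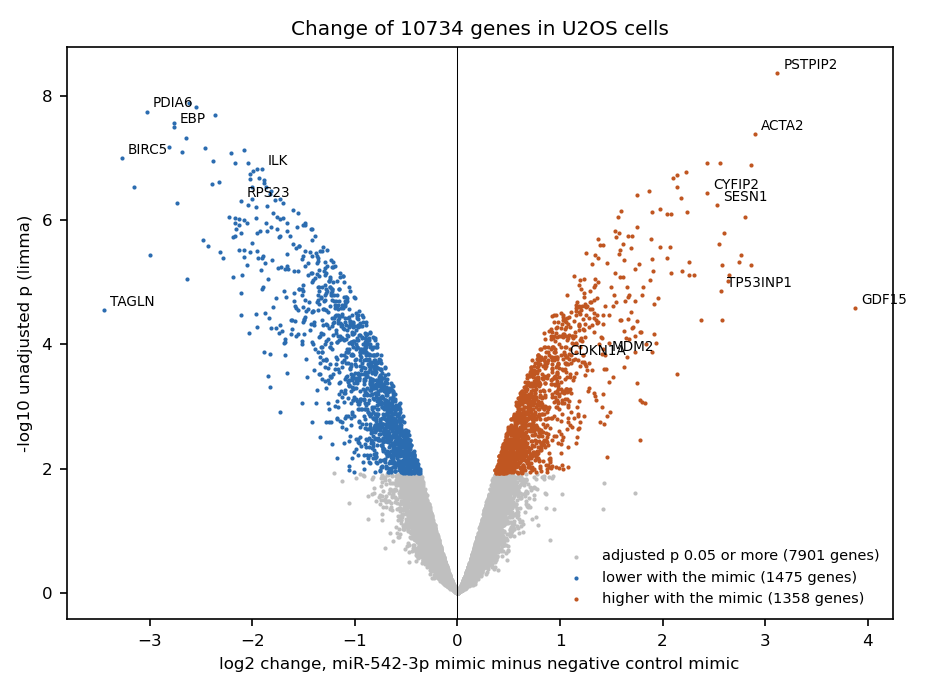
Each point is 1 of 10734 genes, placed by its log2 change (mimic minus control, x axis) and -log10 of its unadjusted limma p (y axis), with 3 arrays per group. The 1475 lower genes are blue, the 1358 higher genes are orange, and BIRC5 and TAGLN lie among the largest falls.

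Of 13 measured genes listed, from general knowledge, as reported miR-542-3p targets, 9 fell, none rose and 4 did not pass the test. The median change was -0.97 (camera adjusted p = 7.6e-06; adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone, 9 were lower and 1, BMP7, was higher. Some members may have been picked from these samples, so the list is not independent evidence of its direction. After BIRC5, the largest falls were found for RPS23, a ribosomal protein, which fell by 2.11 ± 0.15 (SE), and ILK, the integrin-linked kinase, which fell by 1.91 ± 0.12. CTTN, the actin regulator cortactin, fell by 1.86 ± 0.15, and OTUB1, a deubiquitinase, fell by 1.49 ± 0.13. PIM1 fell by 0.97 ± 0.16, and PTGS2, detected on no mimic array, was at least 1.72-fold lower. MRM2 changed by -0.55 and AKT1 by -0.40. The call of AKT1 ended when any 1 array was left out (adjusted p 0.0645 to 0.112), and that of MRM2 without any control array or without mimic replicate 3 (highest adjusted p 0.0955). VANGL2 (-0.13), MRPS10 (-0.15), PIK3R1 (-0.34) and BMP7 (0.52) did not pass. BMP7 was called higher with no background correction (0.29, adjusted p = 0.0461), normexp at an offset of 50 (0.36), the deposited log2 values (0.29), detection on all 6 arrays, eBayes with trend and robust, and array weights (0.67), and without mimic replicate 2 (0.69). PIK3R1 was called lower without mimic replicate 2 (-0.55, adjusted p = 0.0459). With PTGS2 at its bound the list's median was -0.78. With no background correction the median was -0.46, OTUB1 changed by -0.97 and PTGS2 by -0.46.

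Of 41 measured p53 target genes, 38 rose, 1 fell and 2 did not pass the test, with the same counts adjusted over the list alone. The median change was 1.23, or 1.14 with GDF15 and FAS at their bounds (camera adjusted p = 8.3e-22; adjusted p = 0.23 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 1.03 ± 0.16 (SE), and its dimmer probe by 2.38. MDM2, a ubiquitin ligase, rose by 1.44 ± 0.22 and was detected on 2 of 3 control arrays. Its change was 0.63 with no background correction and 0.82 with normexp at an offset of 50. SESN1 rose by 2.53 ± 0.18, CYFIP2 by 2.44 ± 0.16, CMBL by 2.24 ± 0.16, and TIGAR, a regulator of glycolysis, by 2.23 ± 0.14. PMAIP1, which encodes the pro-apoptotic protein NOXA, was the member that fell, by 0.81. Its call ended without control replicate 1 or 3 or mimic replicate 1 or 3 (highest limma adjusted p 0.0723), and with the replicate number as a block (0.0519). TNFRSF10B (0.11) and PTP4A1 (0.25) did not pass.

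**Figure D2:**
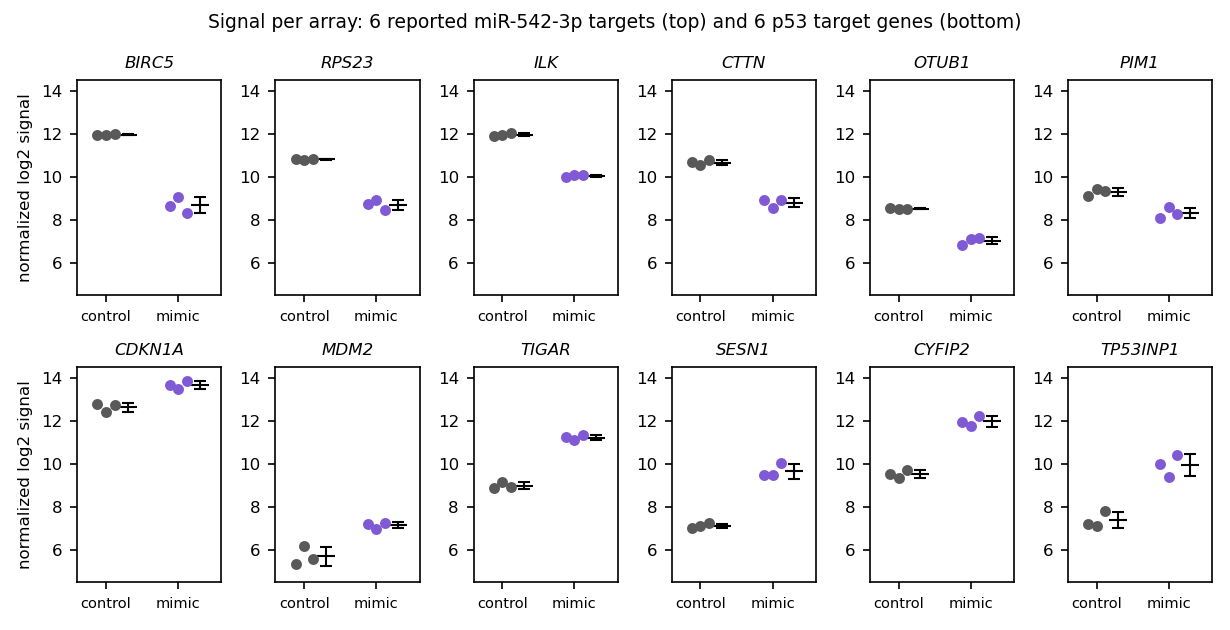
Normalized log2 signal (y axis) of 6 reported miR-542-3p targets (top) and 6 p53 target genes (bottom) on each of 3 control arrays (grey) and 3 mimic arrays (purple), with the mean and SD beside the points. BIRC5 went from a mean of 11.96 to 8.69 and CYFIP2 from 9.55 to 11.98, with no overlap between the groups.

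Of 24 measured genes of cholesterol biosynthesis and its control, 13 fell, 2 rose and 9 did not pass, with a median of -0.63 (camera adjusted p = 1.2e-05; adjusted p = 0.79 with an estimated correlation). Adjusted over the list alone, 15 were lower and 3 higher. Beside EBP, MVK, the mevalonate kinase, fell by 1.90 ± 0.20 (SE), LSS, the lanosterol synthase, by 1.62 ± 0.20, and DHCR7, which makes cholesterol from its last precursor, by 1.51 ± 0.18. MVK changed by -0.98 with no background correction. Dimmer probes of LSS gave -0.49 and -0.29 and were not called. The 2 that rose were PMVK (0.61) and TM7SF2 (0.55). The call of PMVK ended without control replicate 1 or 3 or mimic replicate 2 or 3 (highest adjusted p 0.0793), and that of TM7SF2 without any 1 array other than mimic replicate 1 (highest adjusted p 0.103). With no filter on dim probes both calls ended. The call of TM7SF2 also ended with no background correction (0.25, adjusted p = 0.0634), array medians set equal, the deposited log2 values, eBayes with trend and robust, array weights (0.37, adjusted p = 0.0924) and the replicate number as a block.

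Of 54 measured genes of G1/S and DNA replication, 19 fell and none rose, with a median of -0.32 (camera adjusted p = 1.8e-05; adjusted p = 0.822 with an estimated correlation). Adjusted over the list alone, 22 were lower and 2 higher. The 19 became 10 without control replicate 1 or 2 and 11 without mimic replicate 1 or 3. PCNA, the sliding clamp of DNA replication, fell by 1.18 ± 0.16 (SE), CDK2, a kinase of S-phase entry, by 1.08 ± 0.12, and MCM6, a subunit of the replicative helicase, by 1.06 ± 0.14. Of 61 G2/M and mitosis genes, 16 fell, 1 rose and 44 did not pass, with a median of -0.33 (camera adjusted p = 1.8e-05; adjusted p = 0.822 with an estimated correlation). Adjusted over the list alone, 17 were lower and 1 higher. Without mimic replicate 2, 30 fell and the median was -0.51, and without mimic replicate 3, 10 fell and the median was -0.21. The count was 9 without control replicate 3, and 10 without control replicate 1 or mimic replicate 1. AURKB, a kinase that acts with survivin, fell by 1.08 ± 0.12 and ANLN by 0.98 ± 0.14. TOP2A, the member that rose (0.38), lost its call when any 1 array was left out. The same happened with array medians set equal, cyclic loess, no filter on dim probes or the replicate number as a block (limma adjusted p = 0.0765). For G1/S, another split of the 6 arrays, with mimic and control arrays mixed, gave a larger median (size 0.354).

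The other lists did not pass the camera test, and their members moved both ways or in small number. Of these, fry called the ribosomal (adjusted p = 0.0307), unfolded protein (0.0181), extracellular matrix (0.0475), YAP/TAZ (0.0134), osteoblast (0.0395), TGF-beta (0.0031) and leukocyte (7.0e-04) lists. With no filter on dim probes, camera called the extracellular matrix, YAP/TAZ, hypoxia, oxidative phosphorylation, proteasome and epithelial lists, and without control replicate 3 the extracellular matrix (adjusted p = 0.0327) and proteasome (0.0336) lists. The median differed in sign from the mean or the test for ribosomal proteins, interferon, NF-kB, focal adhesion, autophagy and endothelial lists. Among 43 focal adhesion and integrin genes, 10 fell, ITGB1 by 1.85 ± 0.19 (SE), and 9 rose, CAV2 by 2.04 ± 0.19 (adjusted p = 0.803; 11 lower and 10 higher adjusted over the list alone). The falls numbered 6 without control replicate 1 or mimic replicate 1. Dimmer probes of CAV2 gave 1.06 and 0.03, the last not called. Of 67 cytosolic ribosomal proteins, 7 fell, 1 rose and 59 did not pass (adjusted p = 0.306), with the same counts adjusted over the list alone. RPL22 fell by 2.33 ± 0.15, RPS28 fell by 2.13 ± 0.17, and RPL29 was the member that rose (0.99). RPL23A (-0.44) lost its call when any 1 array was left out (limma adjusted p 0.0517 to 0.0882) and with the replicate number as a block. RPL13 (-0.88) had another probe at 0.41, and lost its call with the mean of probes (-0.23, adjusted p = 0.371). Of 40 unfolded protein and ATF4 response genes, 7 fell and 6 rose, DDIT3 by 1.91 ± 0.19 (adjusted p = 0.744; 8 lower and 6 higher adjusted over the list alone), with 3 rises without control replicate 1. Of 35 hypoxia and glycolysis genes, 7 fell and none rose, PGAM1 by 1.01 ± 0.13 and PFKM by 1.13 ± 0.15 (adjusted p = 0.0675; 9 lower adjusted over the list alone). This list was called with no background correction (adjusted p = 0.0304), normexp at an offset of 50 (0.0376), the deposited log2 values (0.0286), no filter on dim probes (0.0097) and array weights (0.0443). It was also called without control replicate 2 (0.0027, with 11 falls) or mimic replicate 3 (0.0351). Of 32 PI3K, AKT and mTOR genes, 7 fell and 3 rose (adjusted p = 0.734; 8 lower and 4 higher adjusted over the list alone), and 4 fell without control replicate 1 or 3 and none rose without mimic replicate 1 or 3. Only 30 members were measured when any 1 array was left out. PIK3CB, detected on the control arrays alone, gave no value without a control array. INPP5D, detected on the mimic arrays alone, gave none without a mimic array. PHLPP2 fell by 1.86 ± 0.13. Of 38 extracellular matrix genes, 10 rose, FBN2 by 1.36 ± 0.15, and 5 fell, SPP1 by 1.87 ± 0.23 (adjusted p = 0.116; 13 higher and 5 lower adjusted over the list alone). The falls numbered 2 without any 1 control array or without mimic replicate 1. With no background correction PHLPP2 changed by -0.86 and SPP1 by -1.19.

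Of 29 apoptosis regulators, 5 rose, among them BAX (1.14 ± 0.14, SE) and BAK1 (1.22 ± 0.18), and 5 fell (adjusted p = 0.615), with the same counts adjusted over the list alone. The rises numbered 3 without mimic replicate 1 or 3, where FAS, detected on the mimic arrays alone, gave no value. The falls numbered 2 without control replicate 1. A dimmer probe of BAX gave 0.39 and was not called (limma adjusted p = 0.0634). FAS was at least 2.18-fold higher. Of 29 interferon response genes, 4 rose, SP110 by 1.73 ± 0.20, and 5 fell, IFIT1 by 1.13 ± 0.16 (adjusted p = 0.853; 4 higher and 6 lower adjusted over the list alone). The falls numbered 3 without control replicate 1 or mimic replicate 1 or 3. Of 18 NF-kB and inflammatory genes, 3 rose and 4 fell, CCL2 by 1.26 ± 0.20 (adjusted p = 0.803; 4 higher and 4 lower adjusted over the list alone), and 2 fell without control replicate 1 or 2 and 1 rose without mimic replicate 3. PTGS2, detected on the control arrays alone, gave no value without a control array. IL11, detected on the mimic arrays alone, gave none without a mimic array. In the microRNA machinery, 4 of 17 genes fell, AGO1 by 0.73 ± 0.14, and TNRC6A rose by 0.93 ± 0.15 (adjusted p = 0.551; 5 lower and 1 higher adjusted over the list alone). Among YAP/TAZ target genes 5 of 19 rose and 1 fell (adjusted p = 0.153), with the same counts adjusted over the list alone, and none fell without mimic replicate 1 or control replicate 2 or 3. With no background correction the changes were 0.55 for BAK1, 0.68 for FAS, -0.59 for IFIT1 and -0.74 for CCL2.

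In several lists calls ended when 1 array was left out. Among osteoblast genes 3 of 7 rose, RUNX2 by 0.97 ± 0.16 (SE), and 1 fell (adjusted p = 0.615; the same counts adjusted over the list alone). BMP2 and TNFRSF11B both lost their calls without control replicate 1 or mimic replicate 1, which left 1 rise. TNFRSF11B also did so without mimic replicate 2 or control replicate 3 (highest limma adjusted p 0.104), with array medians set equal (0.0502) and with no filter on dim probes (0.0599). BMP2 also did so with no background correction (limma adjusted p = 0.0881), normexp at an offset of 50 (0.0606), the deposited log2 values (0.0876) and eBayes with trend and robust (0.0749). Of 31 proteasome genes 4 fell, PSMB6 by 0.90 ± 0.13 (adjusted p = 0.153; 3 lower adjusted over the list alone). PSME3, PSMB4 and PSMA2 lost their calls without mimic replicate 1, which left 1. The call of PSMB4 ended without any 1 array other than mimic replicate 2 (highest adjusted p 0.0624), and that of PSMA2 without any 1 array other than control replicate 3 (highest adjusted p 0.117). The falls numbered 2 without control replicate 1 or 2 or mimic replicate 3. Of 62 oxidative phosphorylation genes 3 rose and 2 fell (adjusted p = 0.153), but none in either direction adjusted over the list alone. The rises numbered 1 without control replicate 1 or 3 or mimic replicate 1 or 3, and 6 without mimic replicate 2. The falls numbered 1 without any 1 control array or without mimic replicate 1. Of 45 ribosome biogenesis genes 4 rose and 3 fell, IMP4 by 1.07 ± 0.15 (adjusted p = 0.832), with no rise and 2 falls adjusted over the list alone. None rose without control replicate 1 or 3 or mimic replicate 1 or 2. Of 20 heat shock genes DNAJA1 rose and HSPB8 fell (adjusted p = 0.766). The call of DNAJA1 ended when any 1 array was left out (adjusted p 0.0534 to 0.126), and only the fall held adjusted over the list alone. Of 21 replication-dependent histones 2 rose, H2BC5 by 0.98 ± 0.19 (adjusted p = 0.383; 2 higher adjusted over the list alone), and 4 rose without control replicate 2 or mimic replicate 2.

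Of 8 epithelial markers, 2 fell, EPCAM by 1.32 ± 0.19 (SE), and CLDN1 rose by 1.06 ± 0.17, with a list median of -0.37 (adjusted p = 0.153). Of the 8, 7 had negative changes, and adjusted over the list alone 4 were lower and 1 higher. Of 3 leukocyte markers measured, LCP1 fell and the list did not pass camera (adjusted p = 0.153), but fry called it lower (adjusted p = 7.0e-04). Of 3 endothelial markers, VWF was at least 1.54-fold lower (adjusted p = 0.832). LCP1 and VWF, detected on the control arrays alone, gave no value when a control array was left out. Adjusted over the list alone, 1 leukocyte and 1 endothelial marker were lower. With no background correction the changes were -0.70 for EPCAM, 0.45 for CLDN1 and -0.60 for VWF.

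**Figure D3:**
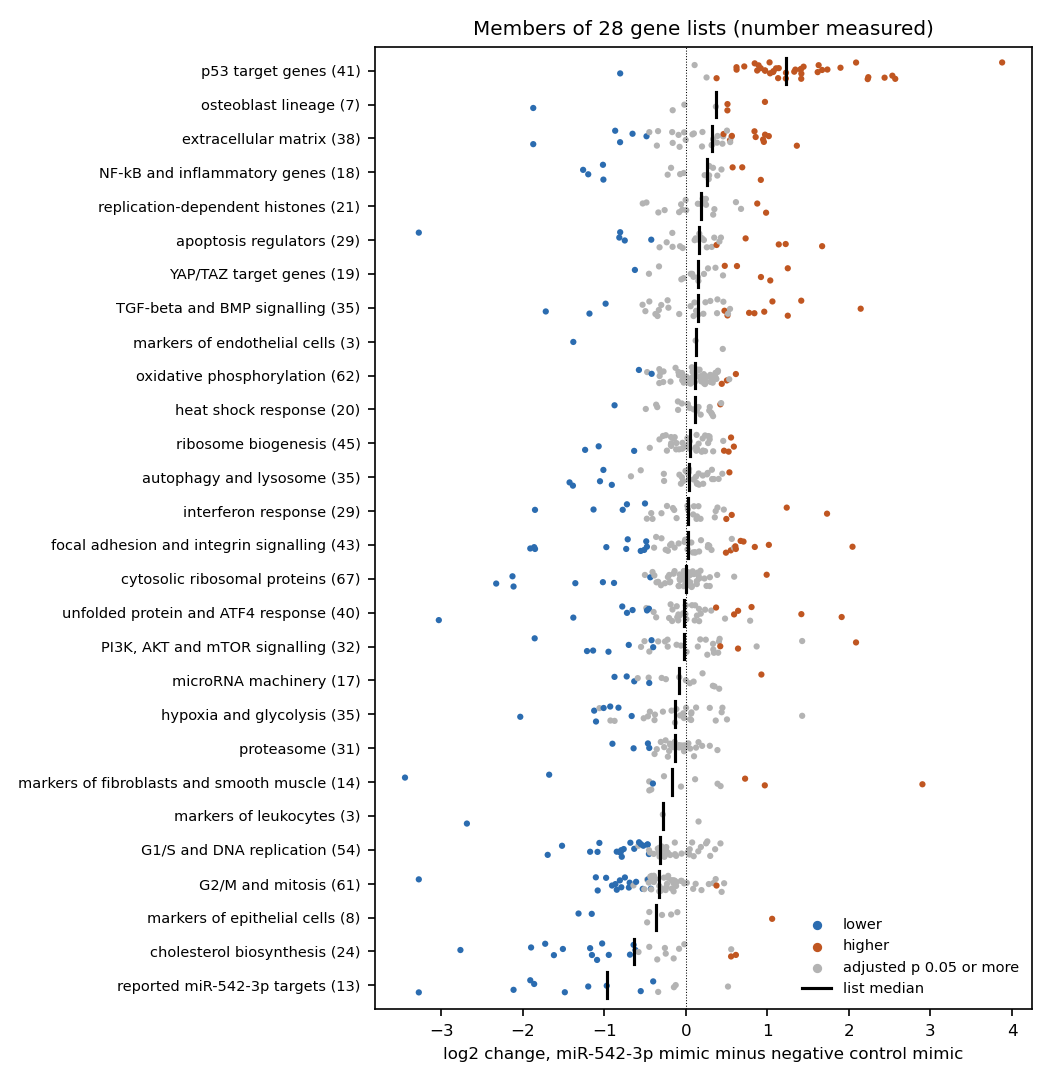
Log2 change (x axis, mimic minus control, 3 arrays per group) of each measured member of 28 gene lists (rows, with the number measured), with called genes in blue (lower) or orange (higher) and the list median as a black bar. The p53 target genes have the highest median, 1.23, and the reported miR-542-3p targets the lowest, -0.97.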

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

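No called list and no called gene, among 140 genes examined, reversed direction in any setting run. Of 136 called genes, 116 stayed called under all 17 settings that gave them a value. Changed genes numbered 2159 to 3838 over the other background steps, normalizations, filters, probe rules, variance models and array weights. At an adjusted p under 0.01 there were 1430 (606 higher, 824 lower), and 1345 (554 higher, 791 lower) with treat at 1.2-fold, since both thresholds are stricter. Leaving out 1 array gave 1860 to 2865 changed genes, 809 to 1335 higher and 1002 to 1530 lower. The fewest came without control replicate 1 (1860, 858 higher) and mimic replicate 1 (1868, 809 higher), and without mimic replicate 3 the higher genes numbered 873. Lists called numbered 11 with no filter on dim probes, 0 with an estimated correlation and 10 by fry, against 5. Fry does not compare a list with other genes, of which 26.4% changed, so its count is of another kind. The 5 lost with an estimated correlation were the reported targets (-0.971, adjusted p = 0.17), p53 targets (1.23, 0.23), G1/S (-0.324, 0.822), G2/M (-0.327, 0.822) and cholesterol biosynthesis (-0.631, 0.792). By fry, G1/S (-0.324, adjusted p = 0.0648) and G2/M (-0.327, adjusted p = 0.0662) were not called. The correlation estimated by camera was 0.448 for G1/S, 0.51 for G2/M, 0.484 for cholesterol biosynthesis and 0.194 for p53 targets, against the preset 0.01. The size of these lists' small camera p-values thus rests on a preset that the estimates exceed. With an estimated correlation, camera also takes its degrees of freedom from the 6 arrays, not from the number of rows. How much each change contributed to the lost calls of these lists was not tested. For the reported targets the estimate was -0.0059, so a correlation above the preset is not why their call ended. That leaves the fewer degrees of freedom, with which their camera p before adjustment went from 5.4e-07 to 6.1e-03. Without BIRC5, an alternative chosen after seeing the data, the reported targets kept their call (adjusted p = 4.4e-05). With the replicate number as a block 2657 genes changed (1261 higher, 1396 lower), 2460 of them also changed the same way without it, and the hypoxia list was called (adjusted p rounding to 0.05). Deviations of same-numbered arrays correlated at 0.02, 0.08 and 0.10, against at most 0.05 for different numbers, and 4 of 6 arrays correlated best with their own number. This hint falls short of the rule that all pairs exceed 0.1, so the arrays were not treated as paired. Fold sizes shrink with no background correction, since background then adds to both groups: of 136 called genes, 44 changed over 1.5 times more with the background step. Low signal over background limits the 71 genes detected on no control array and the 111 detected on no mimic array. A slide block and the seed-match comparison with its alternatives were not run.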

Other observations

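Among 4 genes of actin filaments and contraction, chosen after their values were seen, ACTA2 rose by 2.90 ± 0.15 (SE) on the log2 scale and MYLK, the myosin light chain kinase, rose by 2.31, while TAGLN fell by 3.45 ± 0.41 and CNN1, calponin, by 1.68 ± 0.23, with CNN1 detected on 2 of 3 mimic arrays. With no background correction MYLK changed by 1.30 and CNN1 by -0.79. Among 14 markers of fibroblasts and smooth muscle, 3 rose and 3 fell (camera adjusted p = 0.803; 3 higher and 5 lower adjusted over the list alone). TAGLN also fell by a second probe (-3.99), and a dimmer probe gave -0.31. Of 35 TGF-beta and BMP signalling genes, 9 rose and 3 fell (camera adjusted p = 0.21; 13 higher and 3 lower adjusted over the list alone; fry adjusted p = 0.0031). FST, follistatin, rose by 2.14 ± 0.14, CCN2 rose by 1.25 ± 0.15, and the inhibitors of differentiation ID1, ID2 and ID3 by 0.84, 0.77 and 1.41, while TGFBI fell by 1.72 ± 0.17 and PMEPA1 by 1.18 ± 0.14. PMEPA1 also fell by a second probe (-1.20), and a dimmer probe gave -0.15.

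Of 35 autophagy and lysosome genes, 5 fell and 1 rose (camera adjusted p = 0.734), with the same counts adjusted over the list alone. None rose without control replicate 1 or 3 or mimic replicate 1, and 3 rose without mimic replicate 2. Of the ATG8 family, which coats autophagosome membranes and was singled out after the values were seen, MAP1LC3B fell by 1.39 ± 0.11 (SE), GABARAP by 1.05 ± 0.15 and GABARAPL1 by 0.91, and GABARAPL2 gave 0.04 (adjusted p = 0.885). GABARAP was detected on 1 of 3 mimic arrays, and its change was -0.40 with no background correction. CTSB, a lysosomal protease, fell by 1.43 ± 0.11. Of 2678 genes with more than 1 probe past the filter, 480 had 2 or more probes called the same way and 9 had probes called in opposite directions. Among the 9, UBE2G1 had probes at -1.34 and 0.60, and TNPO1 at 0.59 and -0.93. The probe for the miR-542 precursor was detected on no array.

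The tests of explanations below were chosen after the patterns were seen, with their bounds written before each test's value. That a value had to clear its bound by more than its standard error was added for all of them after the values were seen. It left open the test of the reported targets' probes. The test of neighbouring genes would not clear a margin of 2 standard errors, so it is left open too.

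The p53 target genes rose together, 38 of 41. Array normalization does not account for it: under 5 other scalings and background steps, the list's median less that of all genes stayed at 0.83 or more. Dim probes raised by the background step do not account for it, since the 34 members detected on all 6 arrays at p under 0.01 had a median of 1.12, with 31 higher. A response of this gene group to the mimic may be proposed as a hypothesis. Whether it needs the microRNA's own sequence was not tested beyond the 1 control mimic, and the list's call ended with an estimated correlation.

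BIRC5 lay 2.17 on the log2 scale below PRC1 (-1.11), the lowest other member of the G2/M list. For the reported targets as a set, 1 unreliable probe per gene stays open: 5 of 6 other probes of 5 fallen genes were lower (83.3%, exact 95% interval 35.9 to 99.6%), and 6 probes are too few. Both probes of BIRC5 fell (-3.28 and -3.29), as did both of ILK (-1.91 and -1.73), and 2 of the 3 probes of CTTN (-1.86 and -1.45), the dimmest giving -0.10. Direct action of the mimic on these transcripts was not tested.

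ACTA2 and FAS, adjacent in the order of protein-coding genes, both rose. Over 5822 adjacent pairs of tested genes, log2 changes correlated at r = 0.034 (permutation p = 0.0094, two-sided, 10000 permutations, genes not being independent replicates). The bound set for a general movement of neighbours was an r above 0.1, and the value lay 5.01 SDs of the permuted r below that and 1.19 below 0.05. Whether a general movement of neighbours accounts for the pair is left open, since the value did not clear the wider margin stated above. A correlation over all adjacent pairs also cannot show why this particular pair rose. A shared cause of both rises was not tested.

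The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2833 changed genes and the highest other gave 0, so 1 of 10 splits gave as many. Each other split mixed mimic and control arrays in both groups. The difference between mimic and control then adds to the spread within groups, which lowers the count, and part of it stays in the list medians. The other splits therefore do not show what would be found with no effect. For lists called, the real split gave 5 and the highest other 9, and 6 of 10 splits gave as many. The size of the list median was 1.23 for p53 targets (highest other split 0.53), 0.97 for reported targets (0.46), 0.63 for cholesterol biosynthesis (0.41), 0.327 for G2/M (0.312) and 0.324 for G1/S (0.354).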
